A study of Mus musculus with 6 samples.

How the data were processed

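Gene expression was measured in inferior vena cavae of mice that had been ligated for 24 h, a model of deep vein thrombosis in which stopped flow lets a thrombus form inside the vein. Each sample held the thrombus together with the vessel around it, and 3 thrombi were pooled per sample because single thrombi gave too little RNA, per the labels' design text. A group therefore has 3 pools, and a p-value measures the spread between pools. Control mice were Stingf/f, with a loxP-flanked Sting1 gene, and mKO mice were Stingf/f Lyzm-Cre+/-, with 1 copy of Cre recombinase in the Lyz2 locus, which deletes floxed genes in neutrophils, monocytes and macrophages. Polyadenylated RNA was selected with oligo(dT) beads and sequenced in paired-end reads on a DNBSEQ T7 instrument, per the labels' protocols.

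The authors deposited raw read counts per gene, one table per sample, with no normalization visible in the values. FastQC 0.11.8, Trim Galore 0.4.0, HISAT2 2.1.0, featureCounts 2.0.1 and the mouse build GRCm39 are named in the submitters' processing notes, with no roles or order stated. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The deposited tables list 16533 genes, each paired with its symbol except 13. All 6 tables list the same genes in the same order, and nearly all genes have counts in every library, so the list had been shortened before deposit by a rule that is not given in the sources used here. Because strand is not stated, overlapping and antisense genes cannot be told apart, and near-identical genes, such as the globin, Ifit and Oas paralogs, are uncertain where reads could be split between copies. A reference annotation of an earlier mouse build was matched to 16490 of the gene identifiers, and was used only for chromosome names and for which genes are neighbours; no coordinates are given.

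Library totals ranged from 158579864 to 180068483 counts, and the median gene had 1255 to 1698 counts by library, so counting error is small beside the spread between pools. Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test with TMM normalization, robust dispersion and the default expression filter, which left 16523 genes. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are given as CPM (counts scaled to a common library size) computed from the deposited counts and TMM-scaled library sizes, and log2 fold changes are mKO over control with the standard error (SE) implied by the F-test. For single values, an exact two-sided permutation test over the 10 splits of 6 libraries into 3 and 3 was used; its smallest possible p is 0.1. Replicate tables were compared with each other, and no pair agreed within sampling noise.

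Gene lists for pathways and cell types, 33 in all, were fixed before the data were examined; 32 had at least 5 tested members. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and the rotation test fry were alternatives. Members were also adjusted over the list alone. A list score for a library is the mean log2 CPM of the members relative to the mean over the 6 libraries. A wall score is the mean score of the endothelium, smooth muscle and extracellular matrix lists.

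Genes were named by a rule fixed before the data were examined: Sting1 and Lyz2; up to 8 higher and 8 lower genes by fold change among those past the threshold, or, where none passed, the 5 higher and 5 lower genes with the smallest unadjusted p; and members of the lists, up to 3 past the threshold or the 1 with the highest CPM. No gene passed, so further list members and further genes called by DESeq2 1.42.0 are named below as chosen after their values were seen; some genes that these choices would name are not reported here. Alternatives were other normalizations, other filters, DESeq2, limma voom with and without quality weights, a replicate block, leaving out each library, and leaving out haemoglobin, immunoglobulin and mitochondrial genes. The wall score as a covariate of the list tests, leaving out the 2 libraries with most skeletal muscle transcripts, leaving out the genes near the globin clusters, and the repeats of the DESeq2 counts were added after seeing the data.

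The fits were tested on simulated data for this comparison, with 200 of the 16523 genes changed and the real library sizes and dispersions. In the same simulation a list of 40 other genes was shifted by -0.8 on the log2 scale, and these count as changed below. Of 100 genes changed 2-fold, edgeR recovered 52.0% and DESeq2 74.0%; of 100 changed 4-fold, they recovered 95.0% and 98.0%. With no gene changed, edgeR called 0 genes and DESeq2 called 24. In the simulation with changed genes, 14 of 172 edgeR calls and 43 of 235 DESeq2 calls were genes that had not been changed. Camera was tested on simulated lists of 40 genes drawn independently of each other, which do not have the correlation of real lists. The counts of every simulated gene were drawn independently too. The recovered shares and false calls therefore leave out shifts that many genes share in real libraries.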

Results

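The 6 libraries came from ligated inferior vena cavae with their thrombi, 3 pools from control mice and 3 from mKO mice. Control libraries 1 to 3 held 180068483, 171947534 and 158579864 counts, and mKO libraries 1 to 3 held 172223654, 166879542 and 166083163. Globin transcripts, from red cells in the thrombus, took 24.0% ± 2.40 of the counts in control (SD, n = 3) and 25.8% ± 1.31 in mKO (SD, n = 3). Mitochondrially encoded transcripts took 11.6% ± 2.95 and 9.33% ± 0.863 (SD, n = 3 each). The first principal component held 46.9% of the variance and set mKO library 3 apart from the other libraries. That library had the most skeletal muscle transcript, with Ckm, the muscle creatine kinase, at 37.6 CPM against 0.209 to 9.77 CPM elsewhere. It also nearly lacked transcripts of sympathetic neurons: Th, which makes catecholamine precursors, stood at 0.152 CPM against 16.7 to 52.7 CPM in the other libraries.

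The series compares both genotypes to measure how loss of STING, the adaptor of the cytosolic DNA sensor cGAS, in myeloid cells alters gene expression in the thrombosed vein. The targeted gene Sting1 (ENSMUSG00000024349, chromosome 18) had 27.9 ± 3.21 CPM in control and 24.3 ± 3.87 CPM in mKO (SD, n = 3 each). The log2 fold change was -0.20 (SE 0.14), with an adjusted p of 0.579 by edgeR quasi-likelihood and an exact two-sided permutation p of 0.3. By library, control had 25.1, 31.4 and 27.1 CPM and mKO had 22.7, 21.4 and 28.7 CPM. The count covers the whole gene and every cell of the tissue, so it cannot show a deletion limited to some exons or to myeloid cells. Lyz2 (ENSMUSG00000069516, chromosome 10), the locus that carries Cre, had 1691 ± 235 CPM in control and 981.7 ± 294 CPM in mKO (SD, n = 3 each). Its groups did not overlap, with a log2 fold change of -0.78 (SE 0.26). The adjusted p was 0.333 by edgeR quasi-likelihood, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. Because 1 copy of this locus carries Cre in mKO mice only, a lower Lyz2 count cannot be read as a change in myeloid cells.

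**Figure D1:**
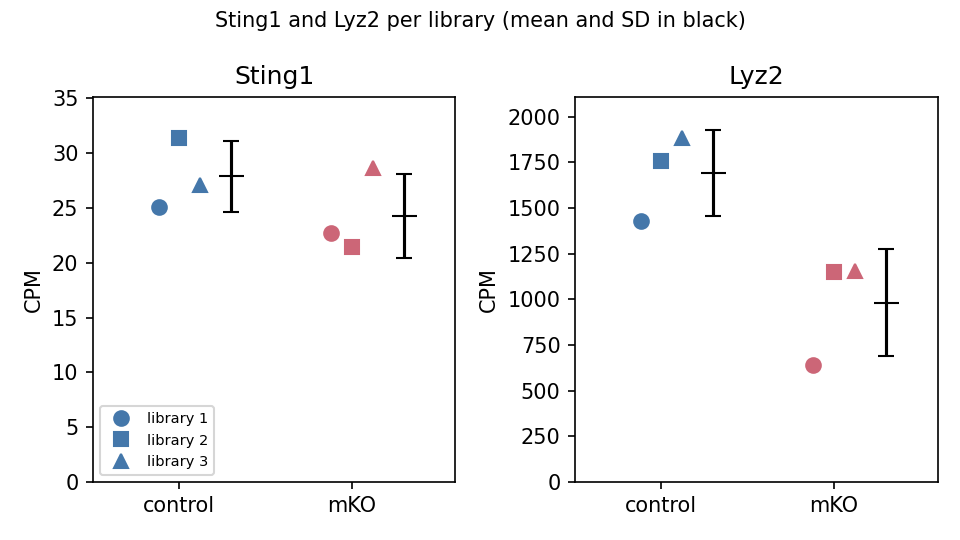
Library-size-scaled counts (CPM) of Sting1 and Lyz2 in each library, with control in blue, mKO in red, one symbol per library number, and the group mean and SD in black (n = 3). Sting1 overlapped between groups, at 21.4 to 31.4 CPM, whereas for Lyz2 every mKO library lay below every control library.

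With camera at its preset correlation, lists of interferon-stimulated, platelet, vessel wall and lymphatic genes were lower in mKO, and lists of erythroid genes and NF-kB target cytokines were higher. None of these calls held with an estimated correlation (smallest adjusted p = 0.679 with an estimated correlation), and the platelet, wall and NF-kB scores overlapped between groups. All 42 measured interferon-stimulated genes had a negative log2 fold change, with a median of -0.80. The inflammatory cytokines Tnf and Il1b had log2 fold changes of 1.02 (SE 0.25) and 0.70 (SE 0.21). By edgeR quasi-likelihood, 0 of 16523 genes had an adjusted p under 0.05, and the smallest was 0.134. At an unadjusted p under 0.05 there were 1960 genes, where 826 would be expected on average with no difference. Single splits of the libraries stray far from that average: those that mix the genotypes gave 103 to 1427 such genes. Limma voom, with or without quality weights, also called 0 genes. DESeq2 called 462 genes, 242 higher and 220 lower in mKO, 130 of them at least 2-fold. The 3 libraries of one group all lay above those of the other for 3000 genes (18.2%), where chance gives 10% on average.

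The 5 higher and 5 lower genes with the smallest p all had an adjusted p of 0.134 by edgeR quasi-likelihood, and so did not pass. By DESeq2 the 5 higher and 5 lower genes all passed, with adjusted p from 3.00e-11 for Ccl24 to 1.29e-05 for Adm. Ccl24, a chemokine that attracts eosinophils, had 2.87 ± 0.239 CPM in control and 7.39 ± 0.976 CPM in mKO (SD, n = 3), with an edgeR log2 fold change of 1.37 (SE 0.16). Tnfaip6, a hyaluronan-binding protein made in inflammation, had a log2 fold change of 0.85 (SE 0.11), and Cd300lb, an activating receptor of myeloid cells, one of 0.93 (SE 0.13). The 2 other higher genes were A530040E14Rik (1.55) and the pseudogene Gpr137b-ps (0.75), whose reads may be shared with its parent gene. The 5 lower genes were Depp1, a FOXO target, at -1.61 (SE 0.19), Sema3g, a semaphorin of arterial endothelium, at -1.46 (SE 0.20), Adm, the vasodilator adrenomedullin, at -0.98 by DESeq2 (SE 0.18), the class Ib histocompatibility gene H2-Q4 at -0.75 (SE 0.11) and the small GTPase Rras2 at -0.72 (SE 0.10). H2-Q4 belongs to a family of similar genes, and its count is uncertain for that reason.

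Genes with the largest fold changes among the DESeq2 calls whose groups did not overlap, and whose mean was at least 1 CPM, were chosen after their values were seen. Among the lower ones, Ucp1, the uncoupling protein of brown fat, had a DESeq2 log2 fold change of -3.30 (SE 0.68), though control library 2 had only 0.417 CPM against 0.183 to 0.295 CPM in mKO, Pck1, of gluconeogenesis and glyceroneogenesis, -1.86 (SE 0.33), and Cidea, a lipid droplet protein, -1.63 (SE 0.35). Gzmb, the cytotoxic protease granzyme B, had -1.65 (SE 0.32), Mfsd4a -1.76 and Ppl -1.66. For Mfsd4a, control library 2 had only 0.795 CPM against 0.609 to 0.753 CPM in mKO. The higher ones included Cma1, the mast cell chymase, at 1.81 (SE 0.51), Jchain, the joining chain of secreted antibodies, at 1.57 (SE 0.27), and Gdf3 at 2.32 (SE 0.63). Slco4a1, Cyp2f2, Tmem273 and Krt18 had values of 1.55, 1.57, 1.53 and 1.46. Stk10 had 4.56 (SE 1.10), but its mKO libraries differed widely, at 1817, 1035 and 60.9 CPM against 37.3 to 49.2 CPM in control, and it lies beside the alpha-globin genes.

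Of the 32 lists tested, 19 passed an adjusted p of 0.05 with camera at its preset correlation, 8 higher and 11 lower in mKO. None of the 19 calls held with an estimated correlation, where adjusted p ranged from 0.679 to 0.882 over the lists. In that setting camera has only the 4 residual degrees of freedom of the design, so its power to call a list is low. The lymphatic list lost its call there although its estimated correlation, -0.070, lay below the preset 0.01. A lost call in that setting therefore does not by itself show that correlation between members explains it. All other called lists had estimates above the preset, from 0.107 for dendritic and mast cell genes to 0.922 for mitochondrially encoded genes. For interferon-stimulated genes the estimate was 0.589. Their camera p-values at the preset thus assume a far lower correlation than was estimated. No list had a member past 0.05 over all genes tested by edgeR, so the member counts below are those adjusted over the list alone, beside 0 over all genes tested; the members given as examples were chosen after their values were seen.

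Type I interferon-stimulated genes fell as a list (median log2 fold change -0.80, camera adjusted p 6.77e-15; adjusted p = 0.679 with an estimated correlation). Of 42 members, 5 were lower adjusted over the list alone and 28 had groups that did not overlap, all lower. The 5 were Oas1g, of the antiviral oligoadenylate synthetases, at -1.53 (SE 0.34), the T cell chemokine Cxcl9 at -1.43 (SE 0.31), Xaf1 at -1.06 (SE 0.23), the guanylate-binding protein Gbp7 at -0.89 (SE 0.22) and Ifit2 at -0.73 (SE 0.14). The list score was 0.82, 0.31 and 0.02 in the control libraries and -0.21, -0.68 and -0.27 in the mKO libraries, so control library 1 carried much of the difference; without it the median was -0.47. The list of STING signalling and nucleic acid sensing genes did not pass (18 members, median -0.21, camera adjusted p 0.115), although its scores did not overlap between groups; it passed without control library 2 (adjusted p 0.0358) and without the 2 libraries richest in skeletal muscle transcripts (0.0481). Its 4 members with the lowest p are interferon-inducible too: Irf7 had a log2 fold change of -1.02 (SE 0.30), Zbp1 -0.96 (SE 0.30), Ifih1 -0.72 (SE 0.19) and Ifi203 -0.61 (SE 0.20), none past 0.05 adjusted over the list alone.

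**Figure D2:**
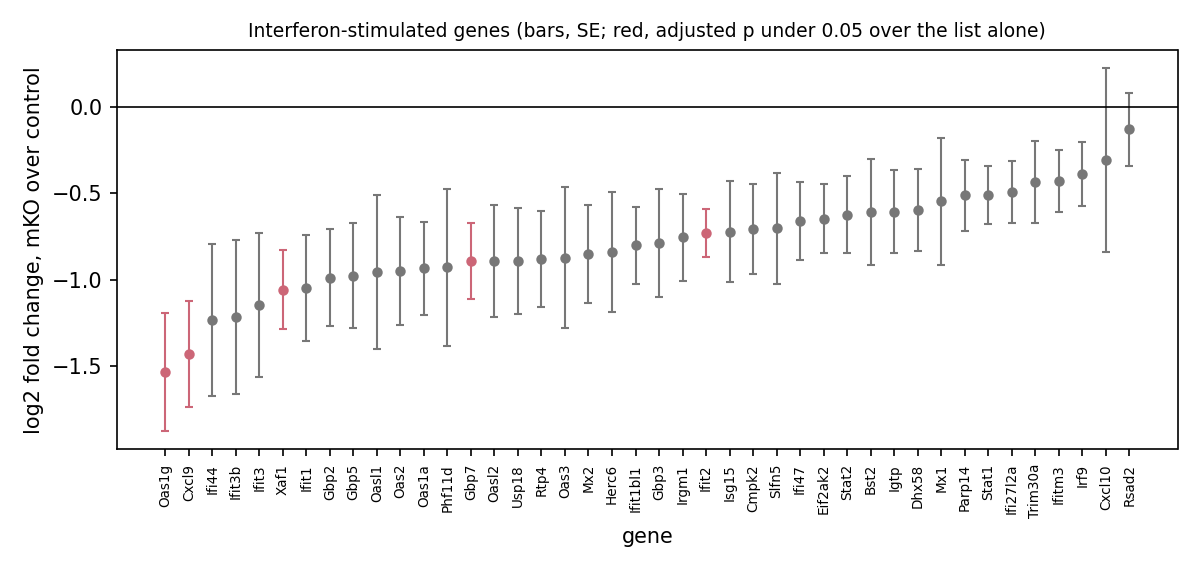
Log2 fold change of the 42 interferon-stimulated genes, mKO over control, by edgeR; bars are SE (n = 3 per group), and the 5 genes in red had an adjusted p under 0.05 over the list alone. All points lie below 0, from Oas1g at -1.53 upward.

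NF-kB target cytokines and mediators rose as a list (30 members, median 0.25, camera adjusted p 1.06e-04; adjusted p = 0.679 with an estimated correlation). Adjusted over the list alone, 8 members were higher and 0 lower, among them Il11 at 1.14 (SE 0.24), Tnf at 1.02 (SE 0.25), Lif at 0.86 (SE 0.21) and Ptgs2, the inducible cyclooxygenase, at 0.55 (SE 0.14). The median was 0.13 without mKO library 1 and 0.38 without mKO library 3. With the wall score as a covariate it was 0.13 (camera adjusted p 0.0239). Immediate early genes passed as higher (25 members, median 0.25, camera adjusted p 0.00339; adjusted p = 0.679 with an estimated correlation), with members in both directions; the call was lost without mKO library 2, where the median was 0.16, and with the wall score as a covariate, where it was 0.07 (camera adjusted p 0.397). Adjusted over the list alone, Egr3 (1.13, SE 0.17) and Nr4a1 (0.57, SE 0.14) were higher, whereas Ccn2 (-1.07, SE 0.26), Ccn1 (-0.69, SE 0.19) and Myc (-0.41, SE 0.10) were lower.

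Neutrophil genes had a median of 0.18 over 40 members (camera adjusted p 0.00222; adjusted p = 0.722 with an estimated correlation), and 0 passed adjusted over the list alone. The alarmin S100a9, at 4767 CPM in control and 6427 CPM in mKO, had a log2 fold change of 0.43 (SE 0.22), and the gelatinase Mmp9 one of 0.79 (SE 0.25). Genes of neutrophil extracellular traps (18 members, median 0.16, camera adjusted p 0.0417) and of inflammasomes and lytic cell death (20 members, median 0.13, camera adjusted p 0.0479) were slightly higher; both had adjusted p = 0.679 with an estimated correlation, and 0 members passed adjusted over the list alone. These 3 calls were lost without control library 2, where the medians were 0.03, 0.09 and 0.10, and with the wall score as a covariate, where the neutrophil median turned to -0.14 (camera adjusted p 0.487). The neutrophil and trap calls were lost also without mKO library 2, and the trap and inflammasome calls without mKO library 1. Monocyte and macrophage genes did not pass as a list (40 members, median 0.03, camera adjusted p 0.344), but adjusted over the list alone 3 were higher and 1 lower. Spp1, osteopontin, rose from 403.1 ± 44.6 to 784.0 ± 78.6 CPM (SD, n = 3; log2 fold change 0.96, SE 0.16), Cd68 had 0.60 (SE 0.15) and Nr4a1 0.57 (SE 0.14), and Lyve1, shared with lymphatic endothelium, had -0.88 (SE 0.13). Chemokines and their receptors did not pass (33 members, median 0.04, camera adjusted p 0.220); adjusted over the list alone, Ccl24 was higher and Ccl5, a chemokine of T cells, was lower at -0.94 (SE 0.19).

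Erythroid genes rose as a list (18 members, median 0.48, camera adjusted p 2.49e-08; adjusted p = 0.679 with an estimated correlation). Adjusted over the list alone, 10 members were higher and 1, Isg20, was lower. Car2, a carbonic anhydrase, had a log2 fold change of 1.19 (SE 0.20), Epb42, of the membrane skeleton, 1.15 (SE 0.22), and Slc4a1, the anion exchanger band 3, 1.05 (SE 0.22). The globin Hbb-bs, by far the most abundant member, had 0.16 (SE 0.20). Platelet genes fell as a list (29 members, median -0.42, camera adjusted p 6.09e-05; adjusted p = 0.679 with an estimated correlation), with 0 members past 0.05 adjusted over the list alone. Pf4, platelet factor 4, had -0.77 (SE 0.25) and the ADP receptor P2ry12 -0.76 (SE 0.24). The platelet median ranged from -0.67 without mKO library 2 to -0.26 without mKO library 1. Coagulation factors (21 members, median -0.16, camera adjusted p 0.134) and fibrinolysis genes (11 members, median -0.01, camera adjusted p 0.880) did not pass, and 0 members passed adjusted over either list alone.

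**Figure D3:**
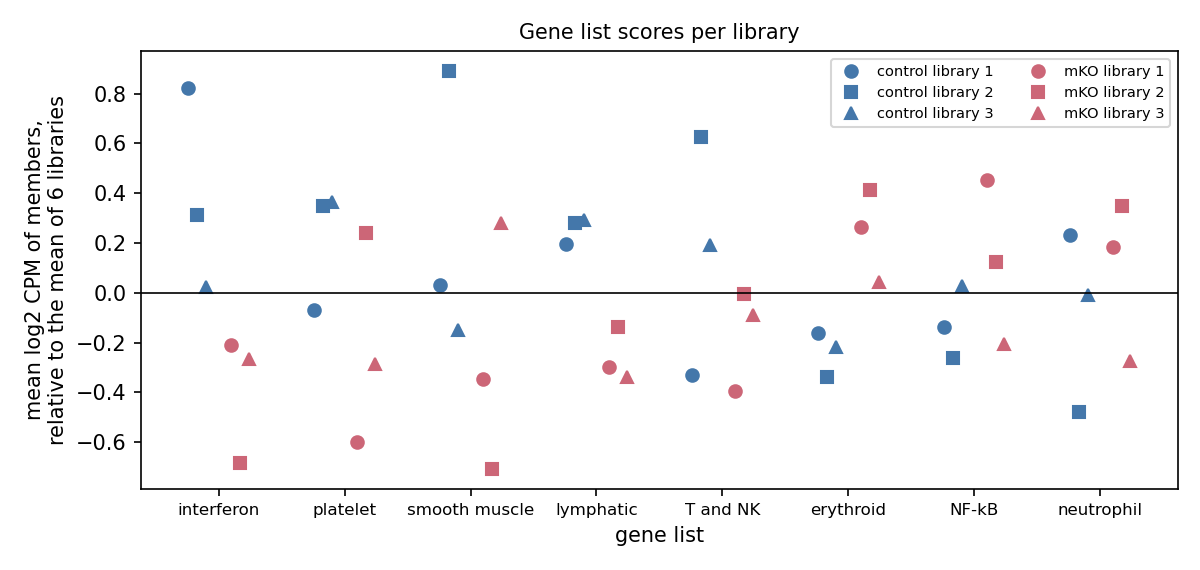
Gene list scores per library (mean log2 CPM of the members relative to the mean of the 6 libraries), with control in blue, mKO in red and one symbol per library number. Of the 8 lists plotted, the groups are separate for interferon, lymphatic and erythroid and overlap for platelet, smooth muscle, T and NK, NF-kB and neutrophil; the interferon score runs from 0.82 in control library 1 to -0.68 in mKO library 2.

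Endothelial genes (31 members, median -0.28, camera adjusted p 3.87e-04), smooth muscle genes (25 members, median -0.49, camera adjusted p 3.87e-04) and extracellular matrix genes (33 members, median -0.41, camera adjusted p 0.00170) fell as lists, each with adjusted p = 0.679 with an estimated correlation. Adjusted over the list alone, 3 endothelial genes were lower: the tight junction gene Cldn5 at -1.22 (SE 0.19), the adrenomedullin co-receptor Ramp2 at -1.06 (SE 0.16) and the transcription factor Sox17 at -0.87 (SE 0.16). In smooth muscle 1 was lower, Pln, the calcium pump regulator phospholamban, at -1.46 (SE 0.29), and in matrix 0. Elastin, Eln, had -1.56 (SE 0.52). The smooth muscle and matrix calls were lost without control library 2 (medians -0.15 and -0.24), and the matrix call also without mKO library 2 (median -0.24); control library 2 had the highest smooth muscle score, 0.89; the endothelial median was -0.11 without mKO library 2. Lymphatic and mesothelial genes fell as a list (9 members, median -0.88, camera adjusted p 0.00497; adjusted p = 0.679 with an estimated correlation), and this list alone passed the directional fry test (adjusted p 0.0194). Adjusted over the list alone, 6 were lower and 2 higher: the lymphatic genes Lyve1 (-0.88, SE 0.13), Flt4, the receptor of VEGF-C (-0.87, SE 0.13), and Prox1 (-0.93, SE 0.22) were lower, and the keratin Krt18 (1.44, SE 0.29) was higher. Matrix metalloproteinases and their inhibitors did not pass (18 members, median 0.07, mean -0.03, camera adjusted p 0.633), although the inhibitor Timp3 was lower adjusted over the list alone, at -1.01 (SE 0.15).

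Among other cell types, T and NK cell genes fell as a list (29 members, median -0.35, camera adjusted p 0.00991, adjusted p = 0.737 with an estimated correlation), with Gzmb alone past 0.05 adjusted over the list alone, at -1.68 (SE 0.31). This call was lost without control library 2 (median -0.17) or mKO library 1, and with the wall score as a covariate (median -0.16, camera adjusted p 0.286). Dendritic and mast cell genes rose as a list (20 members, median 0.49, camera adjusted p 0.00696, adjusted p = 0.679 with an estimated correlation), with 0 members past 0.05 adjusted over the list alone. The members were split, with 13 above 0 and 7 below. Groups did not overlap for 4 higher and 3 lower members, the dendritic cell gene Xcr1 (-0.95, SE 0.31) among the lower. The median ran from 0.31 without mKO library 1 to 0.64 without control library 2, and the list passed on leaving out each library (largest camera adjusted p 0.0472). The call was lost without the 2 libraries richest in skeletal muscle transcripts (median 0.38, camera adjusted p 0.119). The mast cell proteases Cma1 and Mcpt4 had values of 1.80 (SE 0.57) and 1.68 (SE 0.60). In control library 1 they stood at 2.16 and 1.87 CPM, against 0.374 to 0.773 CPM in control libraries 2 and 3. Adipocyte genes fell (24 members, median -0.29, camera adjusted p 0.0193, adjusted p = 0.679 with an estimated correlation), with Cidea lower adjusted over the list alone. This call was lost without control library 2 (median -0.12) or mKO library 2, and with the wall score as a covariate (median -0.13, camera adjusted p 0.801). Nerve and glia genes fell (14 members, median -0.52, camera adjusted p 0.0417; adjusted p = 0.679 with an estimated correlation), with 0 members past 0.05 adjusted over the list alone, and mKO library 3 had a score of -1.64; without it the call was lost and the median was -0.25, and the call was lost also without control library 3 (median -0.21) or mKO library 1. B cell genes did not pass (20 members, camera adjusted p 0.152), and their median of -0.06 and mean of 0.05 differed in sign; Jchain was higher adjusted over the list alone. Skeletal muscle genes did not pass (17 members, median 1.63, camera adjusted p 0.152), and their scores varied between libraries of one group, from -2.03 to 1.66 in control and from -2.01 to 2.92 in mKO. Their median turned to -0.54 without mKO library 3 and was 3.89 without control library 3; the list passed as higher without control library 3, without mKO library 2, with library sizes only (adjusted p 0.0443) and without both muscle-rich libraries (0.0401). Cardiac sleeve genes did not pass (8 members, median -0.45, camera adjusted p 0.0730), with the calcium channel Ryr2 lower adjusted over the list alone at -1.13 (SE 0.30).

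Of the metabolic and stress lists, hypoxia and glycolysis genes rose (28 members, median 0.26, camera adjusted p 3.87e-04; adjusted p = 0.679 with an estimated correlation), whereas Adm, the 1 member past 0.05 adjusted over the list alone, was lower. With the wall score as a covariate the hypoxia median was 0.06 (camera adjusted p 0.504). Mitochondrially encoded genes fell (13 members, all below 0, median -0.27, camera adjusted p 0.00596; adjusted p = 0.680 with an estimated correlation), as did nuclear genes of oxidative phosphorylation (33 members, median -0.12, camera adjusted p 0.0279; adjusted p = 0.737 with an estimated correlation), and 0 members of either passed adjusted over the list alone. These 3 calls were lost without control library 2, without mKO library 2 and with the wall score as a covariate, where the mitochondrial and nuclear lists had camera adjusted p of 0.299 and 0.109. The hypoxia median was 0.13 without mKO library 2, and the mitochondrial median -0.11 without control library 2. The nuclear call was lost also without control library 3 or mKO library 3. Cell cycle genes (28 members, median 0.15, camera adjusted p 0.0523), heat shock and endoplasmic reticulum stress genes (20 members, median 0.08, camera adjusted p 0.209) and growth factor genes (29 members, median -0.03, camera adjusted p 0.633, camera direction higher) did not pass. Adjusted over the list alone, the small heat shock gene Hspb1 was lower at -0.91 (SE 0.20), the receptor Tgfbr1 was higher at 0.71 (SE 0.11), and 0 cell cycle genes passed. Antioxidant genes did not pass (18 members, median 0.00, mean -0.05, camera adjusted p 0.739). In that list the plasma glutathione peroxidase Gpx3 was lower at -1.20 (SE 0.18) and the cystine transporter Slc7a11 was higher at 0.62 (SE 0.14), both adjusted over the list alone. The list of liver, kidney, adrenal and pancreas markers had fewer than 5 members in the tables and was not tested.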

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

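The wall score as a covariate, the settings without the 2 libraries richest in skeletal muscle transcripts and without globin neighbours, and all repeats of the DESeq2 counts, were chosen after seeing the data. The count of 0 genes by edgeR (1960 at an unadjusted p under 0.05) was also 0 with other normalizations, other filters, limma voom with and without quality weights, and without haemoglobin, immunoglobulin and mitochondrial genes or globin neighbours. DESeq2 gave 462 genes, 242 higher, 220 lower and 130 at least 2-fold. Leaving out each library gave 0 to 7 genes by edgeR, 0 to 4 higher, 0 to 3 lower and 0 to 7 at least 2-fold; the 7 came without control library 1. Without the 2 muscle-rich libraries edgeR gave 6 genes, 5 higher, 1 lower and all 6 at least 2-fold, 4 of them globin neighbours (Efcab9, Ubtd2, Stk10 and Sh3pxd2b). The DESeq2 count ran from 243 without control library 2 to 764 without control library 1, with 125 to 490 higher and 99 to 299 lower, and 214 and 364 of the 462 genes were called in those 2 settings. It was 300, with 83 higher, without the muscle-rich libraries; the cause was not tested. Camera called 0 lists, 0 higher and 0 lower, with an estimated correlation, fry 1, 0 higher and 1 lower, and mixed fry 10. With the wall score as a covariate camera called 10 lists, 4 lower: 12 of the 19 calls were lost, the 3 wall lists among them by construction, and cell cycle, B cell and growth factor genes passed as higher. The neutrophil median turned to -0.14 and the smooth muscle median to 0.013. Leaving out each library gave 12 to 21 lists, 6 to 9 higher and 6 to 12 lower, the fewest without control library 2; cell cycle and B cell genes passed as higher without that library, and STING as lower. Cell cycle genes passed as higher and coagulation genes as lower without mKO library 2, and heat shock genes as higher and cardiac sleeve genes as lower without control library 1. The 7 genes that edgeR called without control library 1 included the embryonic globins Hbb-y (3.42) and Hbb-bh1 (3.55). The nerve and glia median turned to 0.26 without the muscle-rich libraries, one of which is the library that nearly lacked neuronal transcripts. Sting1 ranged from -0.34 to -0.11 on leaving out each library and never passed. The genotypes share replicate numbers 1 to 3, but the deviations of same-numbered libraries correlated at -0.14, -0.15 and -0.27, so the numbers were not taken to pair them. With a replicate block edgeR gave 0 genes (1299 at an unadjusted p under 0.05), DESeq2 gave 241, 119 higher and 122 lower, and camera 19 lists, but not the same ones: the inflammasome (adjusted p 0.0532) and oxidative phosphorylation (0.0624) calls were lost, and STING (0.0370) and skeletal muscle genes (5.53e-04) passed. The alternatives for normalized units were not run, since the tables hold counts. With at least 158579864 counts per library, depth limits only the rarest transcripts.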

Other observations

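The tests of control library 1, of myeloid deletion, of blood share and of the globin neighbours were chosen only after the results were seen; the wall score tests were set up after the list results but before their own, and the splits were planned. The blood share test was revised after its first result was seen: its genes went from 4 to all 14 members other than globins, and its upper bound was lowered for a time and then put back. The genotype test of the globin neighbours was widened from Stk10 to all neighbours with a jump, and the SE conditions below were added last.

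Beyond the genotypes, the libraries differed in tissue and in sex. Xist, expressed from the inactive X chromosome of females, had 15 counts in control library 3 and 7254 to 16872 in the other 5 libraries. The Y-linked gene Ddx3y had 4483 to 8210 counts in all 6. By these genes control library 3 was a pool of males, and the other 5 libraries held both sexes. Dbh and Npy, of sympathetic neurons, stood at 0.293 and 4.03 CPM in mKO library 3, against 29.4 to 84.5 and 30.7 to 123.8 CPM elsewhere. Acta1, of skeletal muscle, was highest in mKO library 3 (48.6 CPM) and control library 3 (13.6 CPM).

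The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes by edgeR and the highest other gave 2, so all 10 gave as many. At an unadjusted p under 0.05 the real split gave 1960 and the highest other 1427, and by DESeq2 462 and 98; in each case 1 split, the real one, gave as many. With camera the real split called 19 lists and the highest other 20, so 2 splits gave as many.

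The interferon list was lower in mKO, and 3 explanations stay open. With the wall score as a covariate the median moved from -0.80 to -0.66, and the score difference was -0.61 (SE 0.35), so a smaller share of vessel wall cannot be told apart: the median did not pass its bound of -0.4 by more than that SE. Without control library 1 the median was -0.47 and the score difference -0.56 (SE 0.22), so this library alone is not excluded either. Both medians lay below -0.4 with the list still called by camera, which met the conditions as first written. Only the SE condition added last left both explanations open, and its SE is that of the score difference, not of the median. Camera p-values add little here, since the same test called this list in 6 of the 9 splits that mix the genotypes (adjusted p down to 1.32e-12, medians to -0.67). Deletion of Sting1 in myeloid cells may lower these genes, since STING induces type I interferon, but the exact permutation p of the list score was 0.1, the smallest the design allows.

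The erythroid list was higher in mKO while the adult globins Hba-a1, Hba-a2, Hbb-bs and Hbb-bt had log2 fold changes of 0.09 to 0.26. The embryonic globins Hbb-y and Hbb-bh1 varied within control, at 46.4 and 44.8 CPM in library 1 against 4.57 to 5.45 CPM in libraries 2 and 3, and were not in the comparison below. A larger share of blood could raise both alike. The 14 other members include Isg20, which was lower and so reduces their mean. They exceeded the 4 adult globins by 0.38 on the log2 scale in mKO relative to control (exact permutation p 0.1, the smallest possible). This lies between the bounds of 0.3 and 0.5, so blood share cannot be told apart from a change in red cell precursors. With the wall score as a covariate the median was 0.31 and the score difference 0.34 (SE 0.09). The condition as first written, a median above 0.25 with the list still called by camera (adjusted p 5.79e-05), was met. The median did not pass 0.25 by more than the SE of the score difference, the condition added last, so a smaller share of vessel wall stays open too. Myeloid deletion of Sting1 was not tested for this list.

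Genes next to the globin clusters jumped between libraries. The 10 globins themselves were left out of the comparison, 3 of which jumped too (Hbb-y, Hbb-bh1 and Hbq1a). A jump was a difference of at least 8-fold between libraries with a level of at least 20 CPM. Of 29 other genes within 1 Mb of the alpha- or beta-globin cluster, 9 (31.0%) jumped, against 44 of 16494 genes elsewhere (0.267%). Fisher's exact test gave p 1.68e-16, but it treats genes as independent. Efcab9, Ubtd2 and Stk10 jumped together in mKO libraries 1 and 2. Elsewhere, neuronal genes such as Th and Dbh were low together in mKO library 3. The p-value therefore overstates the evidence. Of the 9, 8 were raised at least 8-fold over their lowest library in mKO libraries only and Sh3pxd2b in both genotypes, and the neighbours' share of all counts was 0.244% to 0.642% in mKO against 0.0790% to 0.219% in control. Efcab9 had 209.8 and 113.7 CPM in mKO libraries 1 and 2 and under 0.1 CPM in the other 4, Sh3pxd2b had 1524 CPM in control library 3 and 22.8 and 25.8 CPM in control libraries 1 and 2, and Fbxw11 had 846.3 CPM in mKO library 2 against 37.5 to 40.7 CPM elsewhere. A candidate explanation is that reads of the abundant globin transcripts were counted in neighbouring genes in some libraries. Genotype as the whole cause is argued against, since in 0 of the 9 did all 3 mKO libraries lie at least 2-fold above every control library, and 5 of the 9 were raised in mKO library 2 alone; a contribution of genotype stays open, given the tally and the shares. Whatever their cause, the jumps make the counts of Stk10 and the other neighbours with a jump doubtful as measures of those genes.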
